A study of Mus musculus with 61 samples.

How the data were processed

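The series followed mouse embryonic fibroblasts through reprogramming to pluripotency, induced with doxycycline from an OKSM cassette (Oct4, Klf4, Sox2 and Myc). The cells carried a hairpin against CAF-1, the histone chaperone complex that assembles nucleosomes on newly replicated DNA, or a control hairpin against Renilla luciferase. Of 61 samples, 6 are Sox2 ChIP-seq libraries, namely 1 immunoprecipitate and 1 input each for Renilla, Chaf1a.166 and Chaf1a.2122 at day 3. Both Chaf1a hairpins target the largest subunit of CAF-1. Another 6 are Sono-seq libraries of day 3, with 3 replicates for CAF-1 knockdown and 3 for Renilla. Sono-seq sequences the DNA released by sonication of cross-linked chromatin, which is richer in accessible regions. The other 49 samples (ATAC-seq, RNA-seq and H3K9me3 ChIP-seq) were not analysed here, so the level of Chaf1a in the knockdown cells was not checked.

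Each Sox2 list holds binding positions of 1 immunoprecipitate against the input of the same hairpin, per the labels. Per the submitters' processing notes, reads were placed on mm9, and BWA 0.7.8 and Bowtie are named without a role. The program that called the positions is not given in the sources used here. Per the file headers, each position has a score, an E-value, a false discovery rate (a q-value), and an enrichment ratio of immunoprecipitate over input with its lower bound. These are the authors' values of single positions, and they were used here only to rank, describe or filter positions within their own list. Every deposited position has a false discovery rate (q-value) below 0.01. Read depth is unknown, so a position missing from a list is one below the threshold of that list, which is no evidence that Sox2 was absent.

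The Sono-seq table holds enhancers and promoters of mouse embryonic stem (ES) cells, taken from a published set per the file headers. Each region has 1 deposited value for CAF-1 and 1 for Renilla. These values were treated as a score, because the sources used here give neither the unit, the scaling, nor the way in which 3 libraries became 1 value. No test between the groups was therefore possible, and the tests planned for single libraries were replaced by a description of the log2 ratio per region. No pseudocount was added, since no value was 0. The table has 22594 rows, 14265 distinct enhancers, 5513 distinct promoter start sites and 5154 gene symbols. Symbols that a spreadsheet had turned into dates (136 rows) were restored through the RefSeq transcript, using a gene table of assembly GRCm38.p6 for names only. Of 5510 transcripts, 5410 were found in it. Regions are given as single positions without an extent, so a Sox2 position within 500 bp counted as lying at the region.

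Positions of the 3 Sox2 lists were pooled and joined into 1 site where neighbours lay within 200 bp, and each site was classed by the lists that hold it. Chance overlap came from 100 sets in which each position moved by 10 kb to 1 Mb. Intervals of counts are exact Poisson and those of shares exact Clopper-Pearson, at 95%, and they cover counting error only. The interval of a median over regions comes from order statistics and takes regions as independent, which neighbouring regions are not. A gene was near Sox2 when a position lay within 10 kb of a start site in the Sono-seq table, because that table alone pairs mm9 start sites with names. The share of each of 9 gene lists near Sox2 was set against all other genes of the table with a two-sided Fisher's exact test, with Benjamini-Hochberg adjustment over 27 tests. The lists were pluripotency, fibroblast, epithelial, Sox2 neural lineage, macrophage and blood, endothelial, muscle, chromatin assembly, and cell cycle. The median Sono-seq ratio of a set of regions was placed among 10000 random sets of the same size, matched on deciles of mean level. Such a percentile also takes regions as independent, so it can be too extreme where a set holds neighbouring regions.

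Groups, gene lists, tests and most alternatives were fixed before the data were examined. So was the rule for named genes. It takes the pluripotency, fibroblast and epithelial lists, the genes nearest to the 5 best-scored positions of 3 site classes, and the 5 highest and 5 lowest Sono-seq ratios among enhancers and promoters in the upper part of mean level (above the median). Alternatives were stricter position thresholds, equal list length (the best 15888 positions of each list), joining distances of 100, 500 and 1000 bp, distances to start sites of 2 and 50 kb, other scalings, and pseudocounts of 0.5 and 5. One listed gene is counted with its list but not reported here by name. The comparison of enhancers with promoters, and the gene list checks that leave out genes, were added after seeing the data.

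The joining of sites was tested on simulated lists of 21350 widely spaced sites with known classes, with positions jittered by an SD of 30 bp. Of each class, 100% was recovered. Such spacing and jitter all but fix this result at a joining distance of 200 bp. It checks the computation and says nothing on sites with close neighbours. In simulated sets of 200 among 14265 enhancers, a shift of 0.1 on the log2 scale put 20 of 20 sets above the 97.5th percentile and a shift of 0.05 put 16 there, against 1 of 20 with no shift. The ratios were shuffled over enhancers and the sets drawn at random. Small sets, sets of neighbouring regions and the lower tail were therefore not checked. A simulated list of 29 among 5154 genes had 60% against 30% near Sox2. Its Fisher p without adjustment was below 0.05 in 91% of 200 draws. The gene lists were judged after adjustment, which was not simulated. Smaller differences, such as 48.3% against 28.4% for pluripotency genes in Chaf1a.166, and lists shorter than 29 genes were not simulated either. The 91% is therefore no measure of what the adjusted tests could detect. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.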

Results

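Sox2 binding was mapped at day 3 of OKSM reprogramming in fibroblasts with a Renilla control hairpin and with each of 2 hairpins against Chaf1a, from 1 immunoprecipitate and 1 input library per hairpin. Sono-seq, a measure of chromatin accessibility, was done at the same day on 3 CAF-1 knockdown and 3 Renilla libraries, of which the deposited table gives 1 value per condition and region. Neither data set therefore has replicate values, and no p-value between conditions is given. Coordinates are mm9, and nearest genes are those among the 5154 genes of the Sono-seq table.

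To ask where Sox2 bound when CAF-1 was reduced, the 3 lists of binding positions were set side by side. The strongest Sox2 sites were occupied in control and knockdown cells alike. They included a site on chromosome 2 at 25036231, 46 bp from the start of Nrarp, which encodes a regulator of Notch signalling. The others of the 5 best shared sites by score in the Chaf1a.166 list were far from listed start sites. The best, on chromosome 10 at 44436601, lay 258108 bp from Prdm1, a transcriptional repressor of the germ line and of blood cells. Those on chromosome 1 at 135294440, chromosome 15 at 39478368 and chromosome 2 at 145888551 had Zbed6, Rims2 and Naa20 as nearest listed genes, 263022, 448491 and 159575 bp away.

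The Renilla list held 17681 Sox2 positions (95% Poisson interval 17421 to 17944), the Chaf1a.166 list 15888 (15642 to 16137) and the Chaf1a.2122 list 19319 (19048 to 19593). The knockdown lists thus lay on either side of the control. Joined within 200 bp, the positions formed 25432 sites, of which 11004 (43.3%, 42.7 to 43.9) were held by all 3 lists. Of the Renilla positions, 69.0% had a Chaf1a.166 position within 200 bp and 76.4% a Chaf1a.2122 position, against 0.343% and 0.426% after random shifts. The 2 knockdown lists shared 79.9% of the Chaf1a.166 positions, against 0.411% by chance. These shares have different bases, 17681 Renilla and 15888 Chaf1a.166 positions, so they do not rank the pairs. In counts, 12199 Renilla positions had a Chaf1a.166 position within 200 bp and 13510 a Chaf1a.2122 position. Of the Chaf1a.166 positions, 12700 had a Chaf1a.2122 position, which lies between these counts. In shared sites with 1 position per list, the positions of Renilla and Chaf1a.166 lay a median of 27 bp apart over 10931 sites.

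Sites present in both knockdowns and missing from the control lay in number between the other pairings in the lists as deposited. The class held 1689 sites, or 31.6% (30.3 to 32.8) of the 5348 sites held by exactly 2 lists. Renilla shared 2482 sites with Chaf1a.2122 alone and 1177 with Chaf1a.166 alone. With lists of equal length the 3 pairings lay closer together and in the same order, at 1538 sites for both knockdowns (33.2%, 31.8 to 34.5), 1659 for Renilla with Chaf1a.2122 and 1442 for Renilla with Chaf1a.166. The order turned with an enrichment lower bound of at least 2, where both knockdowns shared the fewest, at 1195 sites against 1511 and 1431. That bound made Renilla the longest list, at 11545 positions against 11071 (Chaf1a.2122) and 10629 (Chaf1a.166). Among the 5 best sites of both knockdowns by score in the Chaf1a.166 list, one on chromosome 12 at 17542401 lay 9277 bp from Odc1, the rate-limiting enzyme of polyamine synthesis. Another on chromosome 12 at 106002296 lay 12134 bp from Dicer1, which encodes the RNase of microRNA maturation. The sites on chromosome 16 at 29868453 and chromosome 15 at 61938277 were nearest to Hes1, a Notch target, and the non-coding gene Pvt1, at 196989 and 68736 bp. The best-scored of the class, on chromosome 11 at 24051797, ranked only 1965 of 15888 in the Chaf1a.166 list.

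Sites found only with the control hairpin numbered 2982, between the 1997 of Chaf1a.166 alone and the 4101 of Chaf1a.2122 alone. At equal list length the 3 private classes held 2544 (Renilla), 2675 (Chaf1a.166) and 2442 (Chaf1a.2122) sites. With an enrichment lower bound of at least 2, Renilla alone was the largest, at 2670 against 2083 and 2430, and Renilla was then also the longest list. The 5 best-scored Renilla sites had Rel, Rad51l1, Fscn1, Tubd1 and Rab30 as nearest listed genes, at distances from 42297 bp (Tubd1) to 1474127 bp (Rab30). Those near Rel (chromosome 11 at 24051496), Rad51l1 (chromosome 12 at 80534722) and Tubd1 (chromosome 11 at 86400806) became shared by all 3 lists when positions within 500 bp were joined. The sites near Fscn1 (chromosome 5 at 143820634), which encodes an actin bundling protein, and Rab30 (chromosome 7 at 101364350) stayed with the control alone. The best site of both knockdowns, near Rel, merged with the Renilla site in the same way.

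**Figure D1:**
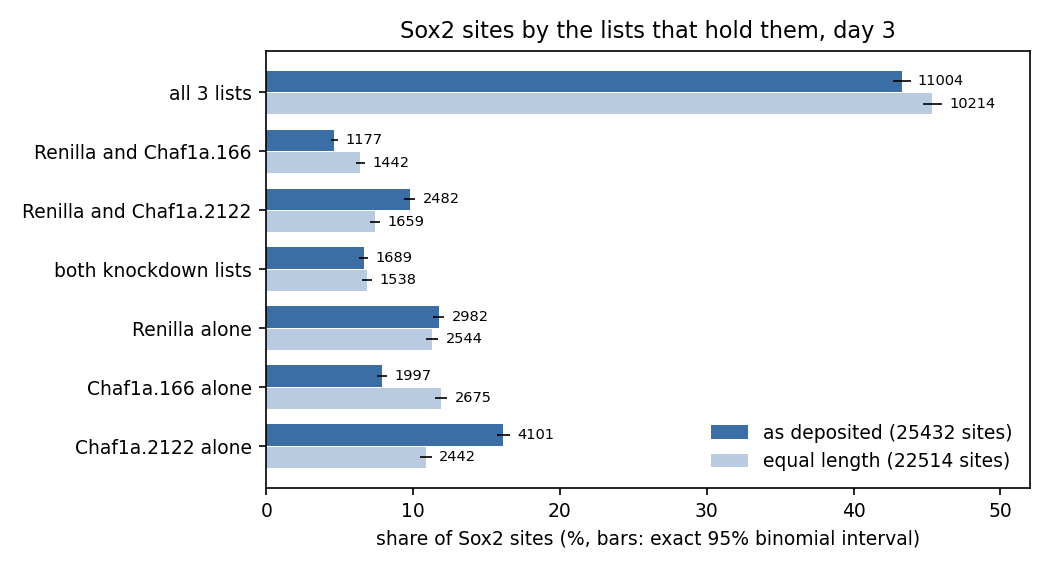
Share of Sox2 sites (%) by the lists that hold them, for lists as deposited and cut to equal length; numbers are sites and error bars exact 95% binomial intervals. All 3 lists held 11004 of 25432 sites, and the 3 pairings held 1442 to 1659 sites at equal length.

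Private positions were the weak ones of each list. By the authors' enrichment over input, which was compared only within a list, Renilla positions in shared sites had a median of 10.3 (quartiles 6.18 and 18.7, n = 11037) and those of Renilla alone 5.40 (3.44 and 8.78, n = 2982). The medians were 9.76 and 5.71 in Chaf1a.166 and 9.63 and 5.12 in Chaf1a.2122. In each list the best 1000 positions by score all fell in sites held by the 3 lists. Of the best 5000, 8 Renilla, 3 Chaf1a.166 and 2 Chaf1a.2122 positions were in that list alone. In the lowest score decile, 51.2% of Renilla, 38.9% of Chaf1a.166 and 57.1% of Chaf1a.2122 positions were private.

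**Figure D2:**
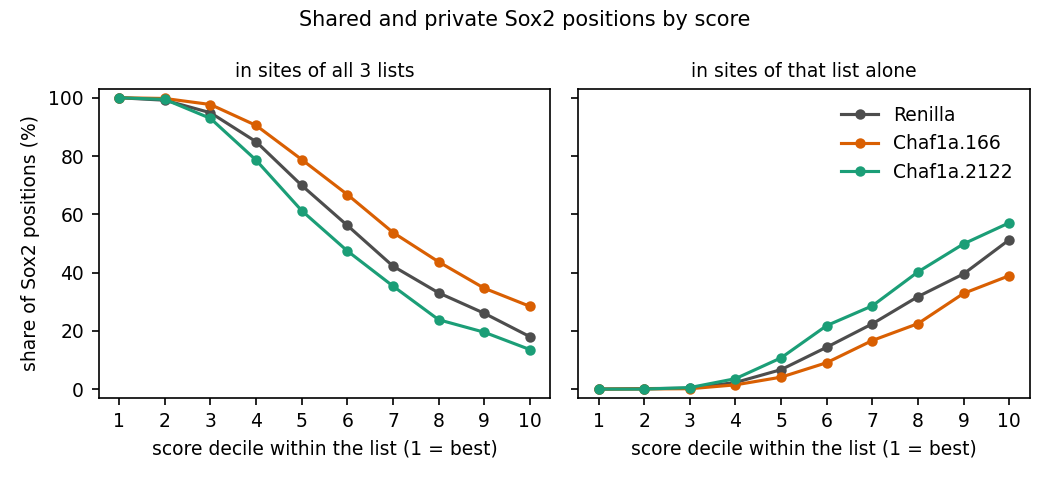
Share of Sox2 positions (%) in sites of all 3 lists (left) and of that list alone (right), by score decile within each list, where 1 is the best. The shared share was 100% in the best decile of each list and fell to 17.99% (Renilla), 28.4% (Chaf1a.166) and 13.6% (Chaf1a.2122) in the lowest.

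Some genes of the pluripotency network had a Sox2 position at day 3 in control and knockdown cells alike. All 3 lists held a position within 10 kb of 9 of the 29 pluripotency genes in the table, namely Pou5f1, Nanog, Fgf4, Fbxo15, Gdf3, Klf2, L1td1, Trim28 and Upp1. At Fgf4, a classic joint target of Oct4 and Sox2, the positions lay 3023 bp (Renilla), 3016 bp (Chaf1a.166) and 3016 bp (Chaf1a.2122) from the start site. At Pou5f1, which encodes Oct4, they lay 1959, 1972 and 1986 bp away, and at Nanog 4488, 4363 and 4519 bp away. The Sox2 gene itself, on chromosome 3, had a position in both knockdown lists, at 34552977 (Chaf1a.166) and 34552964 (Chaf1a.2122), 4051 and 4038 bp from its start site. The nearest Renilla position was 89809 bp away.

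The Chaf1a.166 list alone held positions near Mycn (71 bp), Jarid2 (2680 bp) and Sall4 (5009 bp), among others, and the Chaf1a.2122 list alone near Klf4 (6219 bp). The Mycn position scored 15.0, close to the lowest score of the Chaf1a.166 list (14.8). No list held a position within 10 kb of the other 14, among them Zfp42, Dppa2, Dppa4, Dppa5a, Dnmt3l, Lin28a, Tdgf1, Klf5 and Tet2. In all, 9 of 29 pluripotency genes were near a Renilla position (31.0%, against 29.3% of other genes). For Chaf1a.166 the count was 14 (48.3% against 28.4%) and for Chaf1a.2122 it was 11 (37.9% against 33.3%). None of the 3 shares differed from other genes by Fisher's exact test after adjustment over 27 tests. The lowest p, for Chaf1a.166, was 0.0229, with an odds ratio of 2.36 and an adjusted p of 0.169. Counted within 50 kb, the odds ratios of the lists fell below 1, to 0.468 for Renilla, 0.987 for Chaf1a.166 and 0.683 for Chaf1a.2122, also without an adjusted p under 0.05.

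Fibroblast and epithelial genes were few in this table of ES cell regions, with 3 of 36 and 6 of 20 listed genes. Fn1, the gene of fibronectin, had a Sox2 position 184 bp (Renilla), 216 bp (Chaf1a.166) and 165 bp (Chaf1a.2122) from its start site. Junb, an AP-1 subunit, had positions within 10 kb in every list, at 1282, 1284 and 1312 bp. Tead1, a transcription factor of the Hippo pathway, also had a position in every list, though at different places (5680, 9330 and 1573 bp). By Fisher's exact test the fibroblast list, at 3 of 3 genes, had an adjusted p of 0.169 for Renilla, 0.169 for Chaf1a.166 and 0.200 for Chaf1a.2122. Among epithelial genes, Cdh1 (E-cadherin) and Cldn4 had a position in all 3 lists, at 3622 and 3909 bp in Renilla. Cldn6, a tight junction claudin, had one in both knockdown lists (3406 and 3465 bp), while the nearest Renilla position was 77980 bp away. Epcam, Esrp1 and Esrp2 had none within 10 kb. The epithelial counts were 2 of 6 for Renilla and 3 of 6 for each knockdown, with adjusted p of 1 (exact test).

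**Figure D3:**
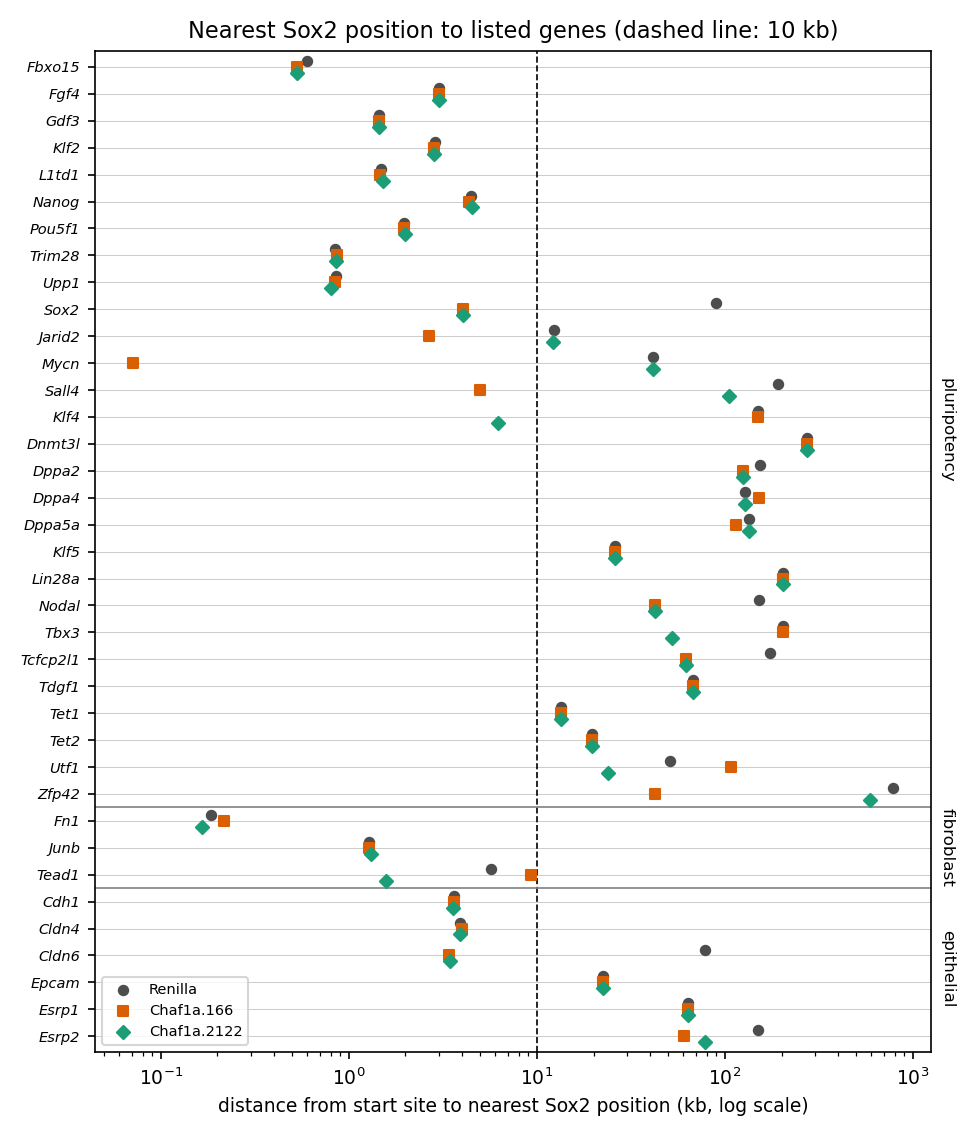
Distance (kb, log axis) from the start sites of reported pluripotency, fibroblast and epithelial genes to the nearest Sox2 position of each list; the dashed line marks 10 kb. All 3 symbols lie left of the line for 9 pluripotency, 3 fibroblast and 2 epithelial genes, and both knockdown symbols without the Renilla one do for Sox2 and Cldn6.

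Across all 5154 genes, the classes were as mixed as the sites. Within 10 kb, 1073 genes (20.8%, 19.7 to 21.95) had a position in all 3 lists and 154 (2.99%, 2.54 to 3.49) in both knockdown lists only. A further 181 had one in Renilla with Chaf1a.2122 only and 87 in Renilla with Chaf1a.166 only. Positions of a single list were found at 168 genes for Renilla, 153 for Chaf1a.166 and 312 for Chaf1a.2122. Sox2 positions were enriched at the listed ES cell regions in every library. Of Renilla positions, 2.61% (2.38 to 2.85) lay within 500 bp of a listed enhancer, against 0.786% after random shifts. The values were 3.00% (2.74 to 3.27) against 0.829% for Chaf1a.166 and 2.75% (2.52 to 2.99) against 0.802% for Chaf1a.2122. At promoters the shares were 2.13%, 2.33% and 2.37%, against 0.271%, 0.284% and 0.273%.

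The Sono-seq comparison asked whether ES cell enhancers and promoters were more accessible in CAF-1 knockdown cells at day 3. The 2 conditions were nearly alike, with a slight tilt of enhancers towards the knockdown. Enhancers had a median log2 ratio of CAF-1 over Renilla of 0.028 (95% interval 0.023 to 0.032, n = 14265 regions), which is 1.02-fold, and 55.3% of them (54.5 to 56.1) were higher with CAF-1 knockdown. Promoters had a median of -0.0093 (-0.017 to -0.0026, n = 5513), and 48.2% were higher (46.9 to 49.5). The enhancer median was above the promoter median on 19 of 20 chromosomes. The difference between them was 0.037 (0.027 to 0.048, from 500 resamplings of chromosomes). Such an interval covers the spread over chromosomes and not that between libraries.

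The spread over single regions was far larger, with an SD of 0.23 for enhancers and 0.23 for promoters. Mean levels over enhancers were 0.141 for CAF-1 and 0.138 for Renilla, and over promoters 0.142 and 0.143, in the authors' values of unstated unit. Because their scaling is unknown, the sign of either median alone carries little weight. Scaled to the same median over all regions, the medians were 0.0088 for enhancers and -0.029 for promoters, and in the upper part of mean level (above the median) the promoter median was 0.011.

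**Figure D4:**
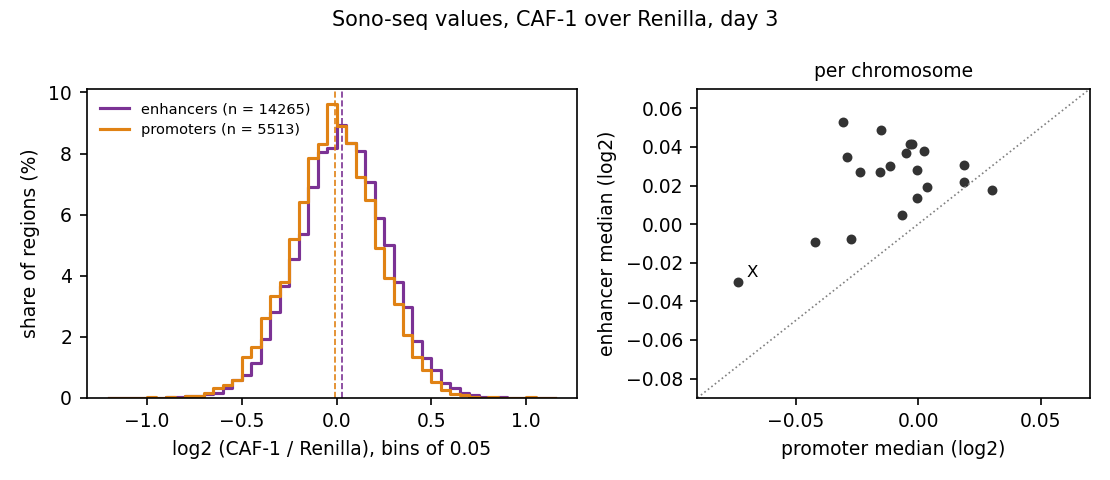
Left, share of regions (%) by log2 ratio of the Sono-seq value, CAF-1 over Renilla, for 14265 enhancers and 5513 promoters, with dashed lines at the medians (0.028 and -0.0093). Right, median of enhancers against median of promoters for each of 20 chromosomes, of which 19 lie above the dotted line of equality.

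Single regions moved both ways. Only 1 promoter and 1 enhancer differed by 2-fold or more. The promoter was that of Dppa2, a gene of early embryos and pluripotent cells, on chromosome 16 at 48310386, with 0.103 in CAF-1 and 0.0507 in Renilla (log2 ratio 1.02). Both values lay below the promoter medians of 0.141 (CAF-1) and 0.143 (Renilla). The enhancer, assigned to Dynlt1b on chromosome 17 at 6404000, had very low values of 0.0130 and 0.0060. Among enhancers above the median level, the highest ratios were assigned to Gpa33 (0.77, chromosome 1 at 168078300), Cux1 (0.76), Rnf8 (0.72), Afap1 (0.72) and Fam83e (0.71). The lowest were assigned to Nsun3 (-0.89, chromosome 16 at 62808150), Skap2 (-0.71), Plin2 (-0.69), Lrrfip1 (-0.67) and Pml (-0.67). Among promoters above the median level, Yme1l1 (0.72) and Mastl (0.60), whose start sites on chromosome 2 at 23012065 and 23011544 adjoin, were high together with Socs1 (0.68), BC011248 (0.63) and Ranbp3 (0.63). The lowest were 2410006H16Rik (-0.87), Snord49b (-0.76) and Snord49a (-0.74), which are 1 locus on chromosome 11 from 62416378 to 62416961, then Nipsnap1 (-0.68) and Zc3h4 (-0.64). With 1 value per condition, none of these regions has a test.

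Promoters of epithelial genes stood out on the higher side. Of 6, 5 had more signal with CAF-1 knockdown, with log2 ratios of 0.59 at Cldn6, 0.44 at Esrp1, 0.31 at Cldn4, 0.30 at Esrp2 and 0.05 at Cdh1. Esrp1 and Esrp2 encode splicing regulators of epithelial cells. Epcam had -0.026. Their median of 0.30 lay at percentile 99.85 of 10000 random promoter sets matched on level, and between percentiles 99.51 and 99.75 when any 1 of the 6 was left out. Their 50 enhancers had a median of 0.055, at percentile 83.2. Percentiles were computed for 12 combinations of list and region type, and they describe these values only.

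Regions of pluripotency genes did not stand apart as a group. Their 175 enhancers had a median of 0.027 (percentile 70.8) and their 31 promoters one of -0.034 (percentile 39.7). The 14 enhancers of Pou5f1 averaged 0.089 ± 0.16 (SD over enhancers), with 11 higher in CAF-1, and the 8 of Fgf4 averaged 0.16 ± 0.24. The 7 enhancers of Sox2 averaged -0.041 ± 0.24, and the 7 of Tcfcp2l1, a transcription factor of naive pluripotency, were all lower, at -0.19 ± 0.20. The 44 enhancers of the fibroblast list had a median of -0.090, at percentile 0.12, with 14 higher in CAF-1. Of these, 36 belong to Tead1 (mean -0.082 ± 0.21), and without them the median of the remaining 8 was -0.015, at percentile 24.9.

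Listed regions with a Sox2 position in at least 1 list had slightly lower ratios than regions without a listed position. The 682 enhancers with a Sox2 position within 500 bp had a median of 0.0059, against 0.029 for the others. The interval of the former (-0.010 to 0.031) includes the latter. Matched sets had a median of 0.034, among which the 682 lay at percentile 0.17. The 719 promoters with a position had a median of -0.031 (-0.055 to -0.0076), against -0.0058 for the others. They lay at percentile 0.925 of matched sets, whose median was -0.011. Where all 3 lists held the site, neither group stood apart from matched sets. The median was 0.017 for 332 enhancers (percentile 13.9), still below the 0.032 of matched sets. It was -0.0011 for 236 promoters (percentile 71.15), above the -0.011 of matched sets. These groups are smaller, and medians of smaller sets vary more, so a lower ratio at shared enhancers is not excluded. At sites of both knockdown lists and not Renilla, 62 enhancers had a median of -0.018 (percentile 5.61) and 56 promoters one of -0.017 (percentile 36.95). At sites of Renilla alone, 61 enhancers had a median of 0.017 (percentile 29.4) and 88 promoters one of -0.071 (-0.13 to -0.0050, percentile 2.12).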

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

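Alternatives for the site classes, Sono-seq medians and gene lists were chosen before the data were examined, and those for the share of pairings, for enhancers minus promoters and for leaving out Tead1 after seeing them. No paired analysis was possible because the Sono-seq table holds 1 value per condition and the Sox2 lists come from 1 library each; leaving out Sono-seq libraries was not run for the same reason. A limit on the false discovery rate of 0.01 and a limit to autosomes and X removed no position. Joining distances of 100 to 1000 bp and equal list length kept each of the 3 planned site classes within 1.5 times its count. Read depth is unknown, which limits any statement on missing positions.

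Stricter thresholds lowered counts by construction. The better-scored part of each list held 8840 (Renilla), 7944 (Chaf1a.166) and 9659 (Chaf1a.2122) positions, with 5921 sites in all 3 lists, 774 in both knockdowns only and 1241 in Renilla alone. An enrichment lower bound of at least 2 left 11545 Renilla, 11071 Chaf1a.2122 and 10629 Chaf1a.166 positions and 5900 shared sites. The share of pairings held by both knockdowns was 28.9% with that bound and 33.2% at equal length. With that bound the order of the classes turned. Both knockdowns (1195 sites) fell below Renilla with Chaf1a.166 (1431) and with Chaf1a.2122 (1511). Renilla alone (2670) rose above Chaf1a.2122 alone (2430) and Chaf1a.166 alone (2083). Renilla was then the longest list. The order of pairings and of private classes followed list length, as it did in the lists as deposited. At equal list length the pairings kept the deposited order. Renilla with Chaf1a.2122 held 35.8% (34.4 to 37.2) of them and Renilla with Chaf1a.166 31.1% (29.8 to 32.4). This argues against length as the whole cause of that order. The private classes changed order at equal length, with Chaf1a.166 (2675) the largest and Chaf1a.2122 (2442) the smallest. Whether length is the cause of the order with the bound was not tested.

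The enhancer median of the Sono-seq ratio was 0.0088 when scaled to the same median, 0.012 quantile normalized, 0.051 in the upper part of mean level, 0.0059 with a pseudocount of 0.5 and 0.00073 with 5. The promoter median was -0.029 scaled, -0.029 quantile normalized, 0.011 in the upper part of mean level, where its sign turned and the cause was not tested, -0.0022 with a pseudocount of 0.5 and -0.00027 with 5. Enhancers minus promoters fell to 0.0082 and 0.0010 with these pseudocounts. That of 0.5 exceeds both values in all but 9 enhancers and 1 promoter. That of 5 exceeds every value, the largest being 4.21. Both thus shrink every ratio. With sites of all 3 lists only, the Sox2-bound regions moved to percentile 13.9 (enhancers) and 71.15 (promoters); the cause was not tested. Odds ratios of pluripotency genes turned below 1 within 50 kb, at 0.468 (Renilla), 0.987 (Chaf1a.166) and 0.683 (Chaf1a.2122), and none passed the adjusted threshold at any distance; the cause was not tested.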

Other observations

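The tests of single Chaf1a lists, of listed genes that lack a Renilla position and of genes with all enhancers on one side were chosen only after the result was seen. Of the 14 listed genes of chromatin assembly 7 were in the Sono-seq table, and 5 of these had a Sox2 position within 10 kb in a knockdown list and none in Renilla. Chaf1b, which encodes the middle subunit of CAF-1, had one in both knockdown lists, 136 bp (Chaf1a.166) and 58 bp (Chaf1a.2122) from its start site on chromosome 16, while the nearest Renilla position lay 118980 bp away. Nasp, a chaperone of H3 and H4, had one at 845 and 747 bp in the same lists. Cabin1 and Daxx had one within 10 kb in Chaf1a.166 only and Pcna, the replication clamp that recruits CAF-1, in Chaf1a.2122 only. Rbbp4, the small CAF-1 subunit, had one in all 3 lists and Atrx in none. That makes 5 of 7 genes for Chaf1a.166 (Fisher's exact p = 0.0228, adjusted p = 0.169), 4 for Chaf1a.2122 and 1 for Renilla. At equal list length Chaf1b and Nasp were no longer near a Chaf1a.2122 position, and the Chaf1a.2122 count fell to 2 of 7 (28.6%, against 28.1% of other genes), so their place in both knockdown lists depends on the longer Chaf1a.2122 list. Their positions also had low scores, at 14.9 (Chaf1b) and 15.6 (Nasp) in Chaf1a.166, where the lowest score was 14.8. In Chaf1a.2122 the scores were 13.1 and 12.9, where the lowest was 12.4. Of 11 cell cycle genes, Mcm3, Aurkb, Trp53 and Top2a were near Sox2 in every list and Mcm2 in Chaf1a.166 only. Few genes of the other lists were in the table: 1 of 3 endothelial and 1 of 2 macrophage and blood genes was near Sox2 in each list, and none of 2 neural lineage genes or of 1 muscle gene.

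In the Sono-seq values, the 29 enhancers of endothelial genes had a median log2 ratio of 0.12 (percentile 94.8), and those of cell cycle, chromatin assembly, macrophage and blood, and muscle genes had 0.026, 0.040, -0.012 and 0.042 (percentiles 47.5, 64.9, 30.2 and 58.1). The 4 neural lineage enhancers had -0.076. Promoters of cell cycle genes had -0.040 and those of chromatin assembly genes -0.058 (percentiles 37.5 and 34.4). Of 466 genes with at least 10 enhancers, 337 had a mean ratio above 0. Some of these genes share enhancers, and the count depends on the unknown scaling of the values. The lowest means were at Irf1 (-0.16 ± 0.23, SD over 13 enhancers) and Slc22a5 (-0.13 ± 0.25, 12 enhancers), which have 11 enhancers in common. All 10 enhancers of Srm, the spermidine synthase gene, were higher with CAF-1 knockdown (0.18 ± 0.11), as were all 8 of Vps37b (0.28 ± 0.14). In all, 9 of 919 genes with at least 7 enhancers had every one higher and 2, Ctnna1 and Tcfcp2l1, every one lower, against 5.23 and 1.04 expected from the share of all enhancers. Fkbp4 and Gm10069, both among the 9, have the same 7 enhancers. With each of 882 distinct sets counted once, 8 were higher throughout and 2 lower, against 4.91 and 0.974 expected. These expected numbers take the enhancers of a gene as independent, which neighbouring enhancers are not, so the counts show no excess. Values on chromosome X were lower than on autosomes, at 0.552 (CAF-1) and 0.562 (Renilla) of the autosomal median at enhancers. Enhancers assigned to Eif4enif1 on chromosome 11 at 3045400, 3089700 and 3076300 had values from 2.84 to 4.21 in both conditions.

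The Sono-seq ratio was higher at ES cell enhancers than at promoters, by 0.037. A trend of the ratio with mean level is argued against as the whole cause, since within deciles of level the difference was 0.041 (0.031 to 0.052). A common scaling of the values cannot make it, because it moves both medians alike. A bias of sequence close to promoters could not be judged: only 11 enhancers lay within 2 kb of a listed start site, and their median minus that of the others was -0.097 (-0.27 to 0.30). A higher accessibility of these enhancers in CAF-1 knockdown cells stays among the open explanations, untested without values per library.

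Positions held by 1 list lay within 1 kb of a listed start site more often than shared ones, at 4.16% against 2.65% in Renilla, 5.26% against 2.65% in Chaf1a.166 and 4.66% against 2.63% in Chaf1a.2122. A low score of private positions may account for it in Renilla, where the odds ratio within deciles of score was 1.01 (0.773 to 1.32). In Chaf1a.166 it stayed at 1.79 (1.34 to 2.38) and in Chaf1a.2122 at 1.32 (1.03 to 1.70), which argues against score as the whole cause there. With 1 library per hairpin, a property of these libraries and a gain of Sox2 at promoters in the knockdown both stay open.

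Of the listed genes, 13 had a Sox2 position within 10 kb that was missing from at least 1 list, and none of the 13 had it in Renilla, against 436 of 1042 other genes (41.8%). Fisher's exact p was 0.0011, from the same genes that showed the pattern, so it does not exclude a chance draw. At equal list length the count was again 0 of 13, against 380 of 926 other genes (41.0%, Fisher's exact p = 0.0013). A cut to equal length cannot add a Renilla position and left the same 13 genes, so this count alone does not exclude different list lengths. Within 2 kb the counts were 1 of 6 and 295 of 742 (exact p = 0.411), and within 50 kb 1 of 14 and 546 of 1186 (exact p = 0.0048). Of the 13, 11 had a Chaf1a.166 position (84.6% against 36.8% of other genes) and 6 one in Chaf1a.2122 (46.2% against 61.5%). The Chaf1a.166 list, at 15888 positions, is shorter than the Renilla list, at 17681. Other genes had a Renilla position more often (41.8%) than a Chaf1a.166 one (36.8%). This argues against different list lengths as the cause for the 11 genes with a Chaf1a.166 position. Whether the lack of Renilla positions is chance, a property of the Chaf1a.166 library or a gain of Sox2 upon CAF-1 loss stays open, with 1 library per hairpin. The rest of the 13, Klf4 and Pcna, kept their Chaf1a.2122 position when that list was cut to 15888 positions. The Renilla list has more positions than that and held none within 10 kb of either gene. This argues against list length as the cause for Klf4 and Pcna as well.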
